A study of Homo sapiens with 6 samples.

How the data were processed

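RNA was sequenced from human pulmonary artery endothelial cells 48 h after transfection with 40 nM of a control siRNA or an siRNA against MED1, with 3 libraries in each group, 6 in all. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the libraries came from separate cultures or donors, so p-values measure only the spread between these libraries, which may be technical.

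The deposited values are RPKM, which scales reads by transcript length and by the mapped reads of the library, with 1 value per gene symbol and library. The submitters' processing notes name TopHat2, an aligner of spliced reads, Cufflinks, which estimates transcript abundance, and the genome build hg38. Their versions, the gene annotation, the filters and any scaling between libraries are not given in the sources used here. RPKM is relative to the total of each library, so a change in abundant transcripts shifts all others, and short or lowly expressed genes have fewer reads behind them than their value shows. No read counts are given, so depth is unknown and no counting interval can be stated. Low values were examined for whole reads. Over genes under 0.08 RPKM in each library, ratios to control replicate 1 had their most common value at 0.900 to 1.20, which would put relative depth at 0.836 to 1.11, but only 9.73% to 30.8% of the ratios within 0.6 log2 units lay within 0.02 log2 units of it. Whole reads were therefore not recovered and no count model was used.

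The table held 23533 symbols. XIST and Y-linked genes, 89 symbols, were left out of every step, and the table has 0 other columns of samples. Of the 23444 symbols used, 19875 were above 0 in at least 1 library, and 12301 had a mean of at least 1 RPKM over the 6 libraries and were tested. In 621 groups of symbols (1438 symbols) the values were identical in all libraries, which fits overlapping genes quantified as a single locus. Among tested genes 1310 symbols did so, in 568 groups, and each symbol was kept as a row, with partners named beside a printed value. Strand use is not stated, so a gene and its antisense partner cannot be told apart.

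MED1 siRNA was compared with control siRNA by limma 3.58.1 (R 4.3.3) on log2(RPKM + 1), with a variance prior that follows mean expression, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Fold changes are differences of that log2 value, which understates the change of low genes. Single genes also had an exact permutation test over the 20 assignments of libraries to groups, whose smallest p is 0.1. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 lists tested. Camera compares a list with the other genes. It was repeated with an estimated correlation, and fry, which tests whether a list moves on balance in a direction without comparing it with other genes, was run beside it. Of the 8 lists called by camera, 7 were called by fry and 0 with the estimated correlation. A list needed 5 measured members. The 29 lists fixed before the data were examined covered receptors, SMAD proteins, BMP targets, TGF-beta targets, ligands and antagonists, endothelial transcription factors, endothelial surface and junction genes, KLF targets, pulmonary arterial hypertension genes, arterial and Notch genes, venous and lymphatic markers, Mediator subunits, nuclear receptors and PPAR targets, G1/S genes, G2/M genes, p53 targets, inflammatory genes, interferon-stimulated genes, endothelial-to-mesenchymal transition, matrix, angiogenesis, cholesterol and lipid synthesis, hypoxia and glycolysis, the unfolded protein and ATF4 response, ribosomal proteins, mitochondrially encoded genes, and the markers of smooth muscle, fibroblasts, and leukocytes and epithelium. The fibroblast, leukocyte and epithelial, and mitochondrial lists were too short to test. A further 8 lists were chosen after the data were seen and form a family of their own.

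The rule for named genes was also fixed before the data were examined. It takes MED1 and 16 fixed genes of BMP signalling and endothelium whatever their values, the 10 largest rises and 10 largest falls among called protein-coding genes with no overlap between groups and at least 2 RPKM in the higher group, and up to 4 members of smallest p in each list. Genes named outside the rule are marked as named after their values were seen, and not every gene the rule takes is printed.

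Gene positions are those of GENCODE release 29 on GRCh38, the build called hg38 in the notes, counted from 1. GC content and length were taken from the longest transcript of each symbol in the same release and matched 97.6% of the tested genes. Alternatives fixed beforehand were pseudocounts of 0.1 and 0.25, no filter, a minimum mean of 5 RPKM, median-ratio scaling, quantile normalization, no variance trend, a robust prior, the replicate number as a block, each library left out in turn and a fold threshold of 1.5. Added after the data were seen were the collapse of identical symbols and a correction for smooth trends on GC content and log2 length (splines with 4 degrees of freedom). On simulated data for this comparison, with 200 of 12301 genes changed, the limma test recovered 51.7% of genes changed 1.5-fold, 82.2% of those changed 2-fold and 97.0% of those changed 3-fold, with 7 false calls (4.29% of its calls). The simulated noise was normal and independent between genes, whereas genes of the real libraries moved together. The simulation also changed a far smaller share of genes than the 29.8% called in the real data. Recovery after Benjamini-Hochberg adjustment depends on that share. These rates therefore need not hold for the real data. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.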

Results

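RNA-seq was used to measure transcript levels in human pulmonary artery endothelial cells (PAECs), the primary cells that line the artery leading from the heart to the lung. Cells received either a control siRNA or an siRNA against MED1, at 40 nM for 48 h, and 3 libraries were made per group. MED1 is a subunit of Mediator, the complex that links transcription factors at enhancers to RNA polymerase II, and the series asks how it acts on BMP and TGF-beta signalling in the endothelium, with pulmonary hypertension in view. The deposited values are RPKM, whose sums over genes were 608478, 581943 and 578160 in control replicates 1 to 3 and 522166, 562972 and 517172 in MED1 siRNA replicates 1 to 3. Depth is unknown, because no read counts are given. Across the 12301 genes tested, Pearson's r on the log2 scale was 0.984 to 0.995 between libraries of the same group and 0.975 to 0.980 between groups, where genes are not independent replicates. MED1 siRNA replicate 2 stood apart from the other libraries of its group in several gene groups, and its values are given where they matter. Each library's deviation from the gene mean was also correlated with transcript length. Spearman's coefficient was −0.325, −0.0736 and −0.0751 in control replicates 1 to 3 and 0.244, −0.0653 and 0.239 in MED1 siRNA replicates 1 to 3. A length trend thus went in part with the group. With GC content it was 0.0156, −0.378 and −0.121 in the controls and −0.254, 0.484 and 0.226 with MED1 siRNA.

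MED1 (chromosome 17, 39404285 to 39451286, minus strand) fell from 9.34 ± 0.395 RPKM (mean ± SD, n = 3, as for each pair of levels here) to 3.28 ± 0.25 RPKM, which was 35.1% of the control level. Its log2 fold change was −1.27 (SE 0.07, adjusted p 0.000299). The MED1 siRNA libraries held 3.04, 3.27 and 3.54 RPKM against 8.98 or more in each control library. The exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 allow. Among the 12301 genes tested, 1368 were higher and 2296 lower with MED1 siRNA, together 29.8%. Changes of at least 1.5-fold were fewer, with 172 genes higher and 606 lower, and of at least 2-fold there were 24 and 175. Lower genes made up 62.7% of the calls on the deposited scale, 51.8% after median-ratio scaling and 46.5% after quantile normalization. They also made up 46.5% after a correction for GC content and length. Among calls of any size, which direction held more genes thus depended on the scaling and on that correction. Because the length trend went in part with the group, bias and treatment cannot be told apart there. Changes of at least 1.5-fold were counted on the deposited scale only, so this dependence was not examined for them. Without control replicates 1, 2 or 3 the count of higher genes was 815, 643 or 748, and without MED1 siRNA replicate 3 it was 643. The count of lower genes was 1323 without control replicate 2, 1284 without control replicate 3 and 1289 without MED1 siRNA replicate 3. Of all 3664 calls, 63.0%, 52.8% and 55.0% were kept without control replicates 1, 2 and 3. Without MED1 siRNA replicates 1, 2 and 3, 76.4%, 95.6% and 51.8% were kept. In these 6 fits 0 calls turned in sign. Fewer libraries give a weaker test, so a call lost in this way need not point to an influential library.

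Called protein-coding genes whose groups did not overlap and whose higher group reached 2 RPKM were ranked on log2(RPKM + 1). Among them the largest rise was in CEBPD, a transcription factor of acute responses, from 26.9 ± 5.36 to 96.2 ± 22.7 RPKM (log2 fold change 1.79, SE 0.20, adjusted p 0.00116). The imprinted gene PEG10 followed (1.57, from 10.3 ± 0.330 to 33.4 ± 9.15 RPKM), and then RRAD, a small GTPase (1.55). CACNG7 and KCNIP4, subunits of ion channels, rose by 1.53 and 1.5 on the log2 scale. As ratios of group means they rose more (3.59 and 4.06) than CEBPD (3.57). BAIAP2L1 rose by 1.43 and the heme-degrading enzyme HMOX1 by 1.40, from 71.8 ± 8.44 to 192 ± 28.9 RPKM. The remaining places among the 10 largest rises belonged to IGF2, INS and INS-IGF2, of which the last overlaps both others, and which hold a single shared value (1.24), so that the gene behind it cannot be told. The largest fall was in TNFSF18, the ligand of the GITR receptor, from 42.9 ± 3.16 to 6.28 ± 1.56 RPKM (−2.61, SE 0.15, adjusted p 0.000299). ITM2A followed at −2.25, then the interferon-induced IFITM1 at −2.19, the protease inhibitor TFPI2 at −2.18 and the cytokine LTB at −2.0. CDC20, CDK1, TOP2A and BIRC5, all genes of dividing cells, fell by 2.05, 1.90, 1.89 and 1.88 on the log2 scale. CXCL11, an interferon-induced chemokine, fell by 1.99 (adjusted p 0.0201), a call that was lost without control replicate 1 (adjusted p 0.0583) or 2 (0.0676), without a filter on low values (0.0579) and with a robust prior (0.0834). MED1 siRNA replicates 1 to 3 held 120, 36.1 and 140 RPKM of IFITM1, against 305 or more in each control library. For CXCL11 they held 14.0, 3.28 and 17.8 RPKM, against 33.1 or more. Replicate 2 thus enlarged both falls.

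**Figure D1:**
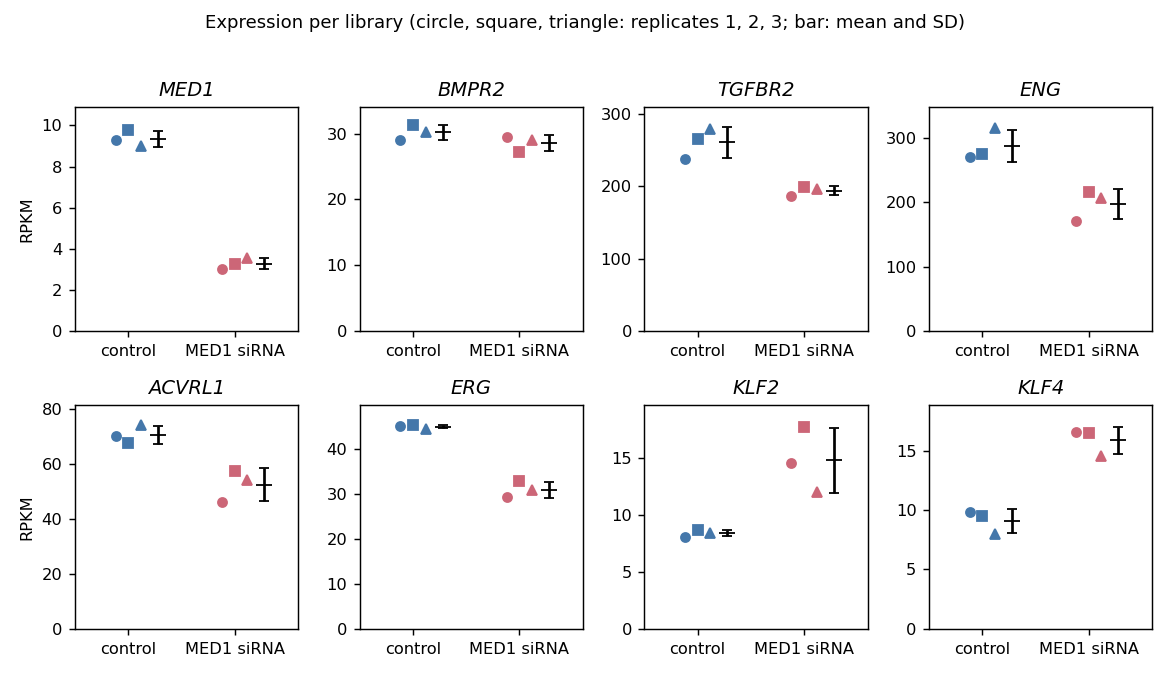
RPKM of 8 genes in each library, on vertical axes that start at 0, for the control siRNA (left) and MED1 siRNA (right) groups, with the mean and SD of 3 libraries beside the points. MED1, TGFBR2, ENG, ACVRL1 and ERG lie lower and KLF2 and KLF4 higher in all 3 MED1 siRNA libraries, whereas BMPR2 overlaps between groups (30.2 and 28.6 RPKM on average).

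Among the receptors of the BMP and TGF-beta families, 3 of the 12 measured fell and 2 rose. TGFBR2, the type II receptor for TGF-beta (chromosome 3, 30606502 to 30694142), fell from 261 ± 21.3 to 194 ± 6.46 RPKM (log2 fold change −0.42, SE 0.08, adjusted p 0.00925). Endoglin, ENG, the co-receptor mutated in hereditary hemorrhagic telangiectasia (chromosome 9, 127815012 to 127854756), fell from 287 ± 24.6 to 198 ± 23.1 RPKM (−0.54, SE 0.11, adjusted p 0.00960). ACVRL1, which encodes the type I receptor ALK1 (chromosome 12, 51906908 to 51923361), fell from 70.6 ± 3.22 to 52.5 ± 5.84 RPKM (−0.43, SE 0.09, adjusted p 0.0118). BMPR2, the type II receptor most often mutated in heritable pulmonary arterial hypertension (chromosome 2, 202376936 to 202567751), stood at 30.2 ± 1.13 RPKM in control and 28.6 ± 1.17 RPKM in MED1 siRNA libraries. That difference did not pass (−0.08, 95% confidence interval −0.22 to 0.07, adjusted p 0.395), and it was 0.01 after quantile normalization. The activin receptor ACVR1B was among those that rose (0.28). The list had a median of −0.07 while its test pointed up, without a call (camera, adjusted p 0.900), and adjusted over the list alone the counts were also 2 higher and 3 lower. After quantile normalization TGFBR2 (adjusted p 0.131) and ENG (0.0612) no longer passed, and without control replicate 3 ACVRL1 did not (0.0522). ACVR1B lost its call without control replicate 2 (0.0618), control replicate 3 (0.0609) or MED1 siRNA replicate 3 (0.0518). Only 1 receptor rose without control replicate 1, control replicate 3 or MED1 siRNA replicate 1, and 0 did without control replicate 2 or MED1 siRNA replicate 3. Without a filter on low values or without a variance trend 1 rose, after the GC and length correction 4 rose, and after quantile normalization 1 fell. The list median ran from −0.10 without control replicate 1 to 0.02 without MED1 siRNA replicate 2, and it was −0.0086 and −0.03 without control replicates 2 and 3.

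The SMAD proteins and their regulators moved up on balance, with 7 of 16 higher and 2 lower, over all genes as when adjusted over the list alone. The median was 0.23 (camera, adjusted p 0.00744), and the adjusted p was 0.658 with an estimated correlation. The transcriptional co-repressor SKI rose from 17.0 ± 1.11 to 28.1 ± 1.41 RPKM (log2 fold change 0.69, SE 0.07, adjusted p 0.000955). The inhibitory SMAD7 rose from 3.01 ± 0.249 to 5.39 ± 0.290 RPKM (0.67) and the receptor-SMAD anchor ZFYVE9 from 8.08 ± 0.413 to 10.9 ± 0.692 RPKM (0.39). Among the SMADs that BMP receptors phosphorylate, SMAD1 was at 20.9 ± 0.508 and 17.2 ± 1.70 RPKM (−0.27, adjusted p 0.0375), a call lost without control replicates 1 (adjusted p 0.0970), 2 (0.12) or 3 (0.0870) or MED1 siRNA replicate 1 (0.0645). It was also lost under median-ratio scaling (0.0752) and quantile normalization (0.0794), without a filter (0.0602) and after the GC and length correction (0.281). SMAD5 (0.06) and SMAD9 (0.20) did not pass, although SMAD5 did after that correction (0.14, adjusted p 0.0482). The count of higher genes was 3 without control replicate 1, control replicate 3 or MED1 siRNA replicate 3, and 4 without control replicate 2, MED1 siRNA replicate 1 or the filter on low values. There was 1 lower gene without control replicate 1 or MED1 siRNA replicate 3, and 0 without control replicate 2, control replicate 3 or MED1 siRNA replicate 1. It was also 1 without a filter, after median-ratio scaling and after the GC and length correction, and 0 after quantile normalization.

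Classical BMP targets did not move together, with 3 of 13 higher and 2 lower (median 0.20, camera adjusted p 0.165, the same counts adjusted over the list alone). Besides SMAD7, the Notch effector HEY1 rose from 2.70 ± 0.230 to 4.66 ± 0.676 RPKM (0.61) and the netrin receptor UNC5B from 2.23 ± 0.304 to 3.71 ± 0.451 RPKM (0.54). ENG was among the lower targets. The ID genes, the most direct readout of BMP receptors, did not pass. ID1 was at 97.1 ± 7.43 and 98.2 ± 16.9 RPKM (0.01, adjusted p 0.978), ID3 at 138 ± 16.9 and 147 ± 27.9 RPKM (0.08) and ID2 at 16.3 ± 0.851 and 24.0 ± 6.78 RPKM (0.49, adjusted p 0.0824). Without MED1 siRNA replicate 2, ID2 passed (0.74, adjusted p 0.000175) while ID1 was at −0.13 and ID3 at −0.06, and ID1 was at −0.06 without control replicate 2. Only 1 target was lower without control replicate 2, control replicate 3 or MED1 siRNA replicate 1, without a filter, and after quantile normalization or the GC and length correction. With a minimum mean of 5 RPKM, 0 were higher and 1 lower, with a median of 0.0056. The list median was 0.09 without MED1 siRNA replicate 2, which stood at 0.273 against 0.054 and 0.082 in replicates 1 and 3.

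Of 17 TGF-beta targets, 4 rose and 3 fell over all genes, and 4 rose and 4 fell when adjusted over the list alone (median −0.05, test pointing up, camera adjusted p 0.876). TGFB2, which encodes a TGF-beta ligand and shares its value with the transcript TGFB2-OT1, fell from 16.1 ± 1.36 to 5.90 ± 0.817 RPKM (−1.31, SE 0.10, adjusted p 0.000478). Ligands and antagonists of the pathway gave 7 lower and 0 higher of 16 (limma, 2 higher at an unadjusted p under 0.05), and the counts were the same adjusted over the list alone. BMP4 fell from 51.3 ± 6.73 to 28.2 ± 4.88 RPKM (−0.85), the extracellular modulator TWSG1 from 44.0 ± 1.47 to 31.5 ± 0.332 RPKM (−0.47) and the activin subunit INHBA by 0.41 on the log2 scale. As a list the ligands did not pass (median −0.04, camera adjusted p 0.393). Of the TGF-beta targets 2 rose without control replicate 1 or 3 and 1 rose without control replicate 2 or MED1 siRNA replicate 3. Without control replicate 2 only 1 fell, and 2 ligands rose without MED1 siRNA replicate 2. Without a filter, or with a minimum mean of 5 RPKM, 2 TGF-beta targets rose, and 1 ligand rose after quantile normalization. The median of the ligands was −0.09 without control replicate 1, −0.10 without control replicate 2, 0.06 without control replicate 3, 0.07 without MED1 siRNA replicate 1, −0.11 without replicate 2 and −0.08 without replicate 3 of that group. After the GC and length correction it was −0.18 (adjusted p 0.0687), after median-ratio scaling 0.0091 and after quantile normalization 0.03. The median of the TGF-beta targets was −0.08, −0.03 and 0.06 without control replicates 1, 2 and 3, 0.03 and −0.02 without MED1 siRNA replicates 1 and 2, and 0.08 after quantile normalization.

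**Figure D2:**
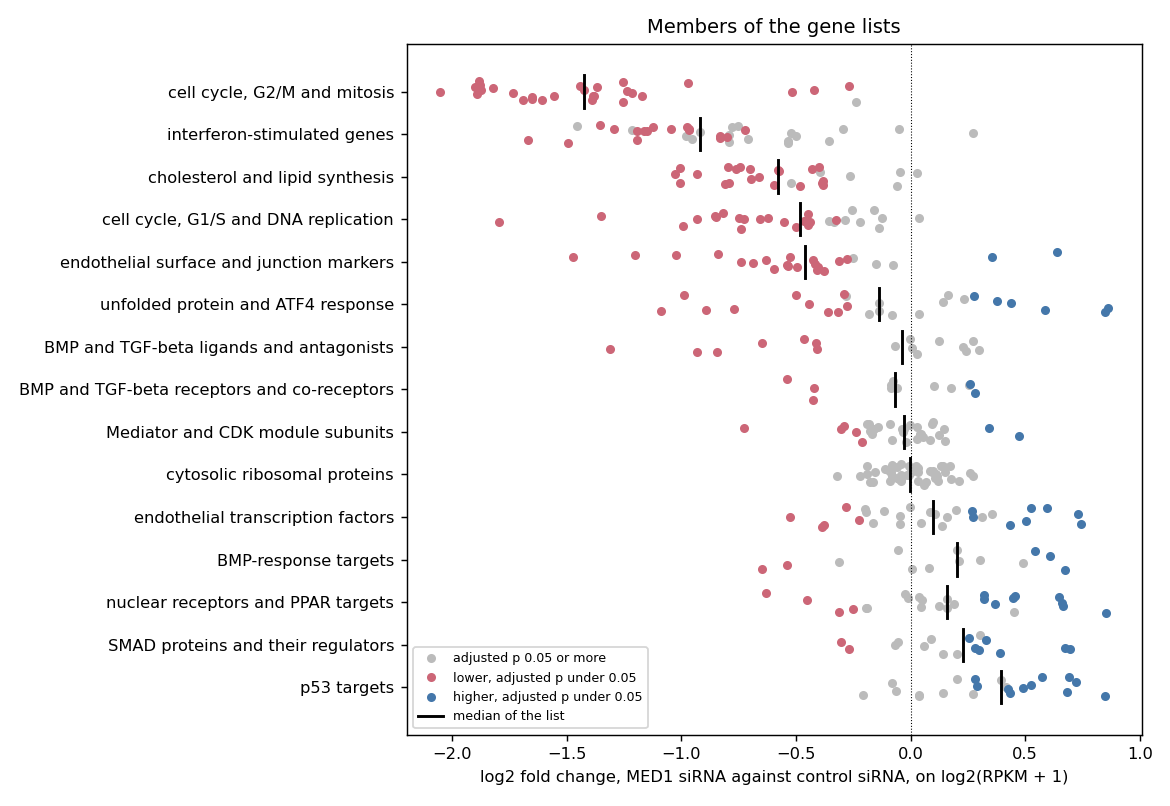
Log2 fold change of each measured member of 15 gene lists (horizontal axis, MED1 siRNA against control siRNA on log2(RPKM + 1)), coloured by whether the adjusted p over all genes was under 0.05, with a black bar at the median of each list. The G2/M list lies lowest, with a median of −1.42, and the p53 list highest, at 0.39.

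Endothelial surface and junction genes fell, with 19 of 24 lower and 2 higher, over all genes as when adjusted over the list alone. The list also held the transcription factor ERG, which is counted here among the lower genes and again with the transcription factors below. The median of the list was −0.46 (camera, adjusted p 3.48e-05), and the adjusted p was 0.658 with an estimated correlation. The sialomucin CD34 fell from 27.8 ± 5.61 to 9.32 ± 1.48 RPKM (log2 fold change −1.47, SE 0.15, adjusted p 0.000893). The junction protein ESAM fell from 109 ± 5.17 to 61.0 ± 8.38 RPKM (−0.84) and PECAM1 from 382 ± 9.63 to 289 ± 6.09 RPKM (−0.40, adjusted p 0.00640). CDH5, which encodes VE-cadherin and shares its value with LINC00920, fell from 342 ± 29.7 to 242 ± 22.8 RPKM (−0.49, adjusted p 0.0105). The tight junction protein CLDN5 was among those that rose, from 58.2 ± 1.13 to 91.1 ± 7.11 RPKM (0.64). The median of the list was −0.29 after quantile normalization, where 8 genes were lower and neither PECAM1 (adjusted p 0.164) nor CDH5 (0.0633) passed. Without control replicate 3 there were 10 lower genes and without MED1 siRNA replicate 3 there were 12. Only 1 gene was higher without any 1 of the 3 control replicates or without MED1 siRNA replicate 3, and without a filter.

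The transcription factors of endothelial identity went both ways, with 8 of 28 higher and 5 lower (median 0.10, camera adjusted p 0.137), and 9 and 5 adjusted over the list alone. ERG, an ETS factor that maintains endothelial genes (chromosome 21, 38380027 to 38661780, minus strand), fell from 44.9 ± 0.400 to 30.9 ± 1.77 RPKM (−0.53, SE 0.06, adjusted p 0.00168). The flow-responsive factors rose. KLF2 (chromosome 19, 16324817 to 16327874) went from 8.41 ± 0.291 to 14.8 ± 2.86 RPKM (0.73, SE 0.12, adjusted p 0.00467), and KLF4 (chromosome 9, 107484852 to 107490482, minus strand) from 9.09 ± 0.984 to 15.9 ± 1.16 RPKM (0.74, SE 0.09, adjusted p 0.00167). The ETS factor ELK3 (0.52) and the forkhead factor FOXC1 (0.60) rose as well. Higher factors numbered 5 without control replicate 3 or MED1 siRNA replicate 3. Lower factors numbered 3 without control replicate 2, control replicate 3 or MED1 siRNA replicate 3 and after quantile normalization.

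Genes known to respond to KLF2 and KLF4 were split, with 4 of 15 higher and 5 lower (median −0.31, camera adjusted p 0.518), and 4 and 7 adjusted over the list alone. The list was not sorted by whether these factors raise or lower a member, so the counts do not measure their activity. EDN1, among the lower ones, fell from 420 ± 35.4 to 301 ± 22.9 RPKM (−0.48). HMOX1 and the KLF genes themselves were among those that rose, whereas caveolin, CAV1, fell from 839 ± 7.84 to 466 ± 69.7 RPKM (−0.86) and the plasminogen activator PLAT from 11.8 ± 1.40 to 7.46 ± 0.302 RPKM (−0.59). NOS3, the endothelial nitric oxide synthase, was at 7.99 ± 1.03 and 5.44 ± 2.42 RPKM (−0.54, adjusted p 0.110), and without MED1 siRNA replicate 2 it passed (−0.83, adjusted p 0.000462), as it did after the GC and length correction (−0.64, adjusted p 0.0424). Without that library 10 KLF targets were lower, and without control replicate 2 or after quantile normalization there were 3, against 8 after the GC and length correction. The median of the KLF targets was −0.17 after quantile normalization. Among 14 measured genes of pulmonary arterial hypertension, 4 fell (CAV1, ENG, ACVRL1 and SMAD1) and KLF2 rose, with a median of −0.08 (camera, adjusted p 0.879), and 2 rose and 5 fell adjusted over the list alone. Without control replicate 3 or after quantile normalization only 2 fell. Without MED1 siRNA replicate 1 or 2, under either other scaling, with a robust prior, with a minimum mean of 5 RPKM, with identical symbols collapsed and after the GC and length correction 2 rose. The median was −0.04 without control replicate 2, 0.03 without MED1 siRNA replicate 2, −0.12 without MED1 siRNA replicate 3 and 0.06 after quantile normalization.

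Of 20 arterial and Notch genes 3 rose and 2 fell (median 0.07, mean −3.21e-04, camera adjusted p 0.253), and 4 and 2 adjusted over the list alone. The gap junction gene GJA5 fell from 7.61 ± 2.16 to 2.03 ± 0.821 RPKM (−1.51), and the Notch coactivator MAML1 rose from 6.69 ± 0.0353 to 9.21 ± 0.151 RPKM (0.41). Only 1 of them fell without control replicate 3, MED1 siRNA replicate 1 or MED1 siRNA replicate 3, and 5 fell without MED1 siRNA replicate 2. Without a filter, with a minimum mean of 5 RPKM and under either other scaling 1 fell. After quantile normalization 5 rose, and after the GC and length correction 6 rose and 5 fell. The median was 0.14 without control replicate 1, 0.17 without MED1 siRNA replicate 1, 0.12 after median-ratio scaling and 0.14 after quantile normalization. Of 5 venous and lymphatic markers 2 fell, also adjusted over the list alone, among them the chemokine receptor ACKR1 (−1.28), whose value is shared with CADM3. The list did not pass (median −0.26, camera adjusted p 0.102). That count was 1 without control replicate 2, control replicate 3, MED1 siRNA replicate 1 or MED1 siRNA replicate 3. The median was −0.13 without MED1 siRNA replicate 1 and −0.15 after quantile normalization. The list passed without MED1 siRNA replicate 2 (0.0496), without a filter (0.0364) and after the GC correction (0.0147). Those calls used the preset correlation. With all 6 libraries the estimated correlation was 0.730 and camera with it gave an adjusted p of 0.832, whereas fry passed (0.0324). Angiogenesis and tip cell genes gave 4 higher and 7 lower of 25, the same adjusted over the list alone (median −0.08, camera adjusted p 0.900). The peptide ligand APLN fell from 120 ± 14.6 to 49.5 ± 7.94 RPKM (−1.26) and FGF2 from 7.47 ± 0.354 to 4.50 ± 0.271 RPKM (−0.62), whereas adrenomedullin, ADM, rose by 0.55. The lower count was 3 without control replicate 3, MED1 siRNA replicate 1 or MED1 siRNA replicate 3, and 4 without a filter or under either other scaling, and 7 rose after the GC and length correction. The median of the angiogenesis list was −0.02 and −0.05 without control replicates 2 and 3 and −0.02, −0.01 and −0.12 without MED1 siRNA replicates 1, 2 and 3, and it was 0.05 after quantile normalization.

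Of 15 genes of endothelial-to-mesenchymal transition, 3 rose and 5 fell, and 3 and 6 adjusted over the list alone (median −0.22, camera adjusted p 0.650). ACTA2, the smooth muscle actin gene, which shares its value with FAS-AS1, rose from 19.3 ± 0.969 to 27.3 ± 1.44 RPKM (0.48), whereas the transcription factor ZEB1 fell from 29.5 ± 2.15 to 21.0 ± 1.36 RPKM (−0.47). Only 1 rose without any 1 of the 3 control replicates or MED1 siRNA replicate 3. Of those that fell, 3 did so without control replicate 2 or MED1 siRNA replicate 1 and 2 without control replicate 3 or MED1 siRNA replicate 3. Without a filter 1 rose and 2 fell, after quantile normalization 5 rose, and 3 fell with a minimum mean of 5 RPKM, after median-ratio scaling and after the GC and length correction. The median was −0.14 without control replicate 3 and −0.10 after quantile normalization. Matrix genes gave 4 higher and 5 lower of 30, the same adjusted over the list alone (median −0.06, camera adjusted p 0.900). The inhibitor TIMP2 rose from 64.9 ± 2.68 to 113 ± 5.11 RPKM (0.79) and the proteoglycan BGN fell from 98.5 ± 14.6 to 53 ± 10.1 RPKM (−0.89). Their higher count was 2 without control replicate 1, control replicate 2 or MED1 siRNA replicate 3, and their lower count was 3 without control replicate 3, MED1 siRNA replicate 1 or a filter. After quantile normalization 7 were higher and 3 lower, and after the GC and length correction 8 were lower (median −0.15). The matrix median was −0.10, −0.09 and −0.01 without control replicates 1, 2 and 3, −0.02 and −0.11 without MED1 siRNA replicates 1 and 3, and 0.02 after quantile normalization.

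Among the lists, genes of cell division had the lowest median. Of 29 measured G2/M and mitosis genes 28 were lower and 0 higher (limma, 0 also at an unadjusted p under 0.05), over all genes as when adjusted over the list alone, with a median of −1.42 (camera, adjusted p 2.2e-18) and an adjusted p of 0.658 with an estimated correlation. The cyclin CCNB1 fell from 19.4 ± 2.87 to 5.44 ± 0.295 RPKM (log2 fold change −1.65, SE 0.10, adjusted p 0.000321). The securin PTTG1 fell from 28.7 ± 2.63 to 10.3 ± 0.762 RPKM (−1.39) and the mitotic kinesin KIF20A from 6.27 ± 0.564 to 0.989 ± 0.316 RPKM (−1.88). CCNB2, named after its value was seen, was at −0.24 and did not pass (adjusted p 0.176), but did without MED1 siRNA replicate 2 (0.00835). With a minimum mean of 5 RPKM, fewer of the genes were tested and 16 were lower. The G1/S and DNA replication genes were also lower, 19 of 28 over all genes and 24 adjusted over the list alone, with 0 higher, also at an unadjusted p under 0.05 (limma, median −0.48, camera adjusted p 3.12e-07, and adjusted p 0.658 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell from 21.7 ± 5.42 to 5.60 ± 1.73 RPKM (−1.80) and the replication factor GINS2 from 6.60 ± 0.981 to 2.07 ± 1.03 RPKM (−1.35). Without control replicate 3, 11 of the G1/S genes were lower, and 1 was higher after the GC and length correction. In that control library the median of the G2/M list was 0.241 above the control mean, and in the others it was −0.090 and −0.125.

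Targets of p53 rose, with 11 of 21 higher and 0 lower over all genes (limma, 0 lower also at an unadjusted p under 0.05) and 13 higher adjusted over the list alone (median 0.39, camera adjusted p 1.71e-06, and adjusted p 0.658 with an estimated correlation). The stress-induced sestrins SESN1 and SESN2 went from 14.5 ± 0.404 to 24.6 ± 2.07 RPKM (0.72) and from 8.90 ± 1.14 to 16.7 ± 0.436 RPKM (0.85). The pro-apoptotic BBC3 rose from 20.6 ± 1.30 to 33.9 ± 2.41 RPKM (0.69) and ZMAT3 from 19.6 ± 0.598 to 29.7 ± 2.67 RPKM (0.57). CDKN1A, the inhibitor of cyclin-dependent kinases, rose by 0.43 on the log2 scale (adjusted p 0.0168), a call that was lost without control replicate 2 (0.0554), control replicate 3 (0.0691) or MED1 siRNA replicate 3 (0.0667). MDM2, named after its value was seen, was at 0.42 and did not pass (adjusted p 0.0798). It passed without MED1 siRNA replicate 2 (0.61, adjusted p 0.000639), after quantile normalization (0.0487) and after the GC and length correction (0.0484).

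Interferon-stimulated genes were lower with MED1 siRNA, 17 of 35 over all genes and 26 adjusted over the list alone, with 0 higher, also at an unadjusted p under 0.05 (limma). The median was −0.92 (camera, adjusted p 1.10e-05), the adjusted p was 0.837 with an estimated correlation, and the self-contained test fry did not pass (adjusted p 0.142). BST2 fell from 516 ± 32.8 to 269 ± 67.6 RPKM (log2 fold change −0.97, SE 0.18, adjusted p 0.00669) and ISG15, a ubiquitin-like modifier, from 1218 ± 194 to 466 ± 214 RPKM (−1.5, adjusted p 0.0148, and 0.0538 without control replicate 1). The libraries differed in size of effect, and without MED1 siRNA replicate 2 the median was −0.51. The list median relative to the control mean was −0.613 in MED1 siRNA replicate 1, −1.64 in replicate 2 and −0.430 in replicate 3, against −0.004, 0.164 and −0.137 in the controls. Lower genes numbered 4, 3 or 5 without control replicates 1, 2 or 3, 11 without MED1 siRNA replicate 1 and 26 without MED1 siRNA replicate 2, where 1 was higher. They were also 4 without a filter on low values, 5 with a robust prior, 8 after quantile normalization and 10 after the GC and length correction.

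**Figure D3:**
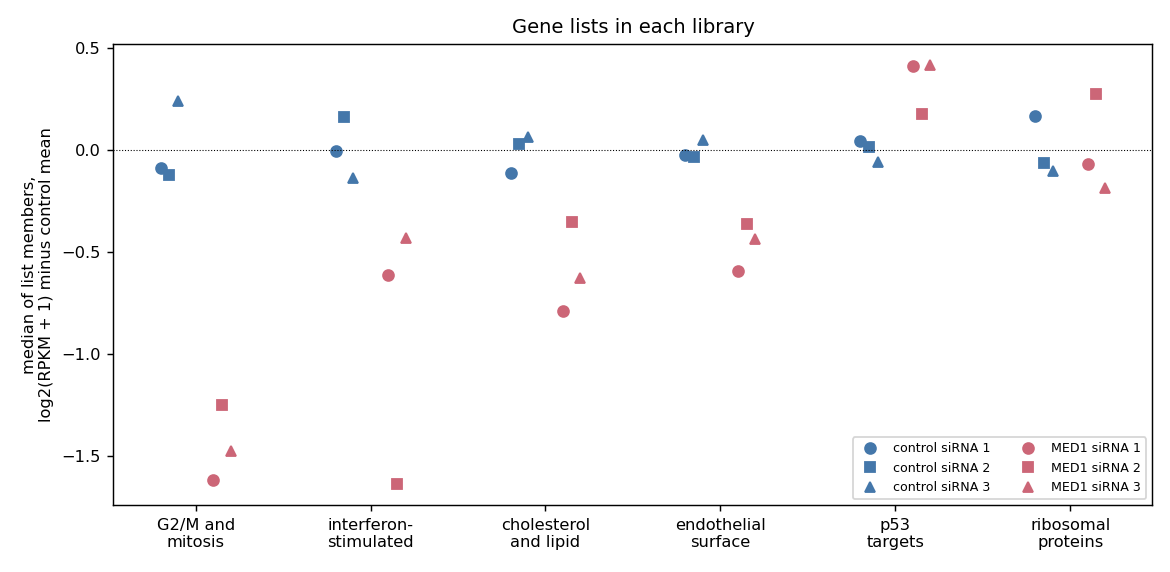
Median of each list's members in every library, as log2(RPKM + 1) minus the control mean (vertical axis), for 6 gene lists, with the control libraries in blue, the MED1 siRNA libraries in red and a marker shape per replicate. MED1 siRNA replicate 2 (red square) is lowest in interferon-stimulated genes, at −1.64, and highest in ribosomal protein genes, at 0.276.

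Inflammatory adhesion and chemokine genes went both ways, with 3 of 27 higher and 4 lower over all genes and 2 and 3 adjusted over the list alone (median 0.12, mean −0.12, camera adjusted p 0.650). The adhesion molecule VCAM1 fell from 37.0 ± 3.00 to 12.3 ± 0.940 RPKM (−1.52, SE 0.08, adjusted p 0.000299), and the NF-kappaB subunit RELB, which shares its value with CLASRP, rose by 0.47. The list median was −0.651 in MED1 siRNA replicate 2 and 0.435 and 0.532 in replicates 1 and 3. Without replicate 2, 14 genes were higher and the list passed (median 0.49, adjusted p 0.0137). That call used the preset correlation. With all 6 libraries the estimated correlation of the list was 0.746, and camera with it gave an adjusted p of 0.958. The median was −0.03 without control replicate 1, −0.07 without MED1 siRNA replicate 1 and −0.06 without MED1 siRNA replicate 3, and it was 0.25 without control replicate 2 or after the GC and length correction, 0.19 without control replicate 3 and 0.21 after quantile normalization. Only 1 gene was higher without any other library, and the lower genes numbered 2 without control replicate 1 or 3 and 1 without control replicate 2. Without a filter 1 was higher and 1 lower, after quantile normalization 5 were higher and 2 lower, and 2 were lower with a robust prior or after the GC and length correction.

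Cholesterol and lipid synthesis genes fell, with 21 of 27 lower over all genes and 24 adjusted over the list alone, and 0 higher, also at an unadjusted p under 0.05 (limma, median −0.58, camera adjusted p 1.26e-07, and adjusted p 0.658 with an estimated correlation). HMGCS1 fell from 50.7 ± 7.30 to 24.8 ± 4.55 RPKM (−1.01) and ACLY, which makes cytosolic acetyl-CoA, from 68.7 ± 2.93 to 33.7 ± 2.93 RPKM (−1.01). Members of the unfolded protein and ATF4 response were split, with 6 of 25 higher and 10 lower, and 6 and 11 adjusted over the list alone (median −0.14, camera adjusted p 0.515). The chaperone HSP90B1 fell from 433 ± 20.8 to 203 ± 3.42 RPKM (−1.09, adjusted p 0.000321) and the disulfide isomerase PDIA6 from 282 ± 20.2 to 141 ± 3.45 RPKM (−0.99), whereas SESN2 rose. The higher count was 3 without control replicate 2, control replicate 3 or MED1 siRNA replicate 3. The median was −0.09 after quantile normalization and −0.07 after the GC and length correction. Hypoxia and glycolysis genes gave 6 higher and 7 lower of 27, and 6 and 8 adjusted over the list alone (median −0.11, camera adjusted p 0.747). The collagen hydroxylase P4HA1 fell from 30.2 ± 1.05 to 17.7 ± 0.903 RPKM (−0.74) and LDHA by 0.46 on the log2 scale. The lower count was 4 without control replicate 1, control replicate 3, MED1 siRNA replicate 1 or MED1 siRNA replicate 3, and without control replicate 2 both counts were 3. After quantile normalization 3 were lower and the median was 0.0052, and it was −0.17 without MED1 siRNA replicate 3.

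Nuclear receptors and PPAR targets, which MED1 is known to bind or serve, gave 9 higher and 4 lower of 25, the same adjusted over the list alone (median 0.16, camera adjusted p 0.0234, and adjusted p 0.658 with an estimated correlation). The lipid droplet protein PLIN2 rose from 24.9 ± 1.76 to 40.1 ± 5.21 RPKM (0.66), the orphan receptor NR4A1 from 1.17 ± 0.234 to 2.94 ± 0.601 RPKM (0.85) and the glucocorticoid-induced FKBP5, which shares its value with LOC285847, by 0.65. The retinoic acid receptor RARB fell from 2.96 ± 0.272 to 1.56 ± 0.143 RPKM (−0.63). Without control replicate 2 the median was 0.09 (adjusted p 0.0479). The list did not pass without a filter (0.0537) or after the GC and length correction (0.136). Its lower count was 1 without control replicate 3 or MED1 siRNA replicate 3 and 2 without control replicate 1, control replicate 2 or MED1 siRNA replicate 1. It was also 2 without a filter, with a minimum mean of 5 RPKM and after median-ratio scaling, and 1 after quantile normalization. Of 31 other Mediator and CDK module subunits 2 rose and 5 fell, and 2 and 3 adjusted over the list alone (median −0.03, camera adjusted p 0.959). MED11 fell from 7.90 ± 0.562 to 4.4 ± 0.752 RPKM (−0.73), and the kinase CDK19 rose from 2.26 ± 0.182 to 3.52 ± 0.0600 RPKM (0.47). The lower count was 3 without control replicate 1, 2 without control replicate 2 or 3 and 1 without MED1 siRNA replicate 3. It was 3 without a filter, without a variance trend and under either other scaling. The higher count was 0 with a minimum mean of 5 RPKM, and after the GC and length correction 7 were higher and 1 lower, with a median of 0.07. The Mediator median was −0.0059 without control replicate 1, 0.01 after median-ratio scaling and 0.02 after quantile normalization. None of 49 cytosolic ribosomal protein genes passed in either direction (limma, 0 also adjusted over the list alone and at an unadjusted p under 0.05, median −0.00, camera adjusted p 0.515), but 9 were higher after quantile normalization (adjusted p of the list 0.00302) and 6 lower without MED1 siRNA replicate 2. After the GC and length correction 1 was higher. The ribosomal list passed without control replicate 1 (0.0373) or MED1 siRNA replicate 3 (0.0205). These calls, and that after quantile normalization, used the preset correlation. With all 6 libraries the estimated correlation was 0.928, and neither camera with it (adjusted p 0.958) nor fry (0.984) called the list. Its median ran from −0.13 without MED1 siRNA replicate 2 to 0.10 without replicate 3 of that group, was 0.09, −0.04 and −0.06 without control replicates 1, 2 and 3 and 0.03 without MED1 siRNA replicate 1, and was 0.15 after quantile normalization.

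Markers of other cell types were looked at in the same libraries. Of 6 smooth muscle and pericyte markers 2 rose and 2 fell, also adjusted over the list alone (median 0.16, camera adjusted p 0.515), with ACTA2 up as above. The higher count was 1 without any library other than MED1 siRNA replicate 1, and the lower count was 0 without control replicate 2, control replicate 3, MED1 siRNA replicate 1 or MED1 siRNA replicate 3. Without a filter 1 was higher and 0 lower, with a minimum mean of 5 RPKM 1 was higher, and after quantile normalization 1 was lower. The median was 0.06 without MED1 siRNA replicate 2, which stood at 0.290 against 0.070 and 0.046 in replicates 1 and 3, and 0.28 after quantile normalization. Only 2 of 11 fibroblast markers reached the minimum level, of which COL1A2 fell from 1.84 ± 0.340 to 0.873 ± 0.263 RPKM (−0.60), and adjusted over the list alone both were lower. Of 12 leukocyte and epithelial markers 3 were measured, with 1 higher and 2 lower, also adjusted over the list alone. They were the keratin KRT18, which fell from 30.9 ± 4.34 to 21.4 ± 1.34 RPKM, CD68, which shares its value with MPDU1 and fell by 0.42 on the log2 scale, and KRT8, which rose by 0.37 but did not pass without control replicate 2 (0.114), control replicate 3 (0.101) or MED1 siRNA replicate 3 (0.0663), or without a filter (0.0775). Mitochondrially encoded genes were not among the symbols of the table and were not analysed here.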

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

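The GC and length correction and the collapse of identical symbols were chosen after the data were seen. MED1 stayed lower and past the threshold under all 17 alternatives. The counts of higher and lower genes, 1368 and 2296, were 172 and 606 with a fold threshold of 1.5, 2190 higher after the GC and length correction (2802 of the 3664 calls kept, 20 turned in sign), and 643 to 1776 higher and 1284 to 3055 lower when single libraries were left out. Whether the replicate numbers pair the samples is not known from the labels. Residual correlations of same-numbered libraries were −0.172, −0.371 and 0.0918, and not every library correlated best with its own number. These values give no sign of pairing but cannot exclude it. With 3 libraries per group, 1 outlying library can sway them. With the replicate block, 761 genes were higher and 1444 lower, with 3 higher and 0 lower of the SMAD list, 0 higher receptors, 2 higher TGF-beta targets, 3 lower endothelial transcription factors, 1 higher endothelial surface gene, 1 lower arterial gene, 2 lower Mediator subunits, 2 lower nuclear receptor genes, 3 lower mesenchymal, 4 lower angiogenesis, 4 lower hypoxia and, of the added lists, 5 lower translocon, 1 lower proteasome, 0 lower RNA polymerase II and 5 higher clock genes. With an estimated correlation the adjusted p was 0.658 for the SMAD, endothelial surface, nuclear receptor, G1/S, G2/M, p53 and cholesterol lists and 0.837 for the interferon list, which fry put at 0.142. The shared 0.658 is a tie made by the adjustment. Before it, camera gave 0.0578 for p53, 0.0963 for G2/M, 0.0966 for nuclear receptor and 0.160 for SMAD genes. For the endothelial surface, G1/S and cholesterol lists it gave 0.167, 0.194 and 0.202. The estimated correlations of these 8 lists ran from 0.0382 (nuclear receptor) to 0.912 (interferon). The cause was not tested for the changes above or for the following ones. Without a filter the receptor (0.909) and TGF-beta target (0.977) lists turned direction uncalled, the venous list passed (0.0364) and the nuclear receptor list did not (0.0537), and the added RNA polymerase II list turned (0.818). With a minimum of 5 RPKM the receptor and TGF-beta target (both 0.878), matrix (0.962) and angiogenesis (0.990) lists turned uncalled and the endothelial transcription factors passed (0.0366). The Mediator list turned after median-ratio scaling (0.880) and GC correction (0.427). Quantile normalization turned the matrix (0.864), angiogenesis (0.965) and hypoxia (0.888) lists uncalled, called the ribosomal list (0.00302) and put BMPR2 at 0.0070. GC correction turned the receptor and TGF-beta target lists (both 0.829), called the venous list (0.0147) and ended the nuclear receptor call (0.136). Under fry the receptor (0.464), TGF-beta target (0.683) and inflammatory (0.799) lists pointed the other way uncalled, and the venous (0.0324), hypoxia (0.0216) and unfolded protein (0.0185) lists passed. Leaving out single libraries gave adjusted p of 0.773 to 1.00 for receptors, 0.594 to 1.00 for TGF-beta targets, 0.0205 to 0.919 for ribosomal proteins, 0.880 to 1.00 for Mediator, 0.571 to 0.972 for matrix, 0.0137 to 0.975 for inflammatory genes, 0.618 to 0.972 for angiogenesis, 0.653 to 0.919 for pulmonary hypertension genes, 0.0496 to 0.191 for venous markers and 0.496 to 0.969 for RNA polymerase II. Over the same settings log2 fold changes were −0.0012 to 0.11 for SMAD5, −0.13 to 0.10 for ID1 and −0.062 to 0.20 for ID3. Of 1894 comparisons of printed genes with an alternative, 1848 kept direction and side of the threshold, 33 lost the call, 8 gained one and 5 turned direction. Of 645 for lists these numbers were 582, 18, 11 and 34. The unknown depth limits what can be said of genes near 1 RPKM.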

Other observations

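The 8 gene lists in the next 2 paragraphs were chosen after the data were seen, and so were the tests on replicate 2 and, for the endothelial genes, on scaling and on other cells. Because the lists were drawn up with the changes of single genes in view, their p-values describe these genes and carry no weight as tests. Of 16 endoplasmic reticulum chaperones and disulfide isomerases 14 were lower, with a median of −0.49 (camera, adjusted p 8.19e-08, and adjusted p 0.160 with an estimated correlation). P4HB, a disulfide isomerase, went from 414 ± 27.1 to 225 ± 17.5 RPKM (mean ± SD, n = 3), and the isomerase PDIA4 from 102 ± 7.20 to 54.2 ± 3.59 RPKM. The count of lower chaperones was 9 without control replicate 3. Parts of the translocon and signal peptidase, which bring new proteins into that compartment, were lower in 8 of 15 cases (median −0.29, adjusted p 0.000115, and 0.0996 with an estimated correlation), with SSR1 from 50.9 ± 0.971 to 31.0 ± 0.674 RPKM. That count was 5 without control replicate 1, control replicate 2 or MED1 siRNA replicate 3, 5 under both other scalings and 4 after the GC and length correction. The median of this list was −0.12 after quantile normalization (adjusted p 0.00375) and −0.18 after the GC and length correction (adjusted p 0.00127). Genes of MHC class I presentation were lower in 10 of 15 cases (median −0.62, adjusted p 7.15e-05, and 0.381 with an estimated correlation), with HLA-C from 547 ± 28.1 to 282 ± 76.6 RPKM and the immunoproteasome subunit PSMB10 from 36.9 ± 4.61 to 24.0 ± 2.67 RPKM. HLA genes resemble each other closely, so reads can be split among them. The medians of this list were −0.564, −1.02 and −0.465 in MED1 siRNA replicates 1 to 3. Core proteasome subunits were lower in 8 of 14 cases (median −0.25, adjusted p 0.000603, and 0.160 with an estimated correlation), but in 0 after quantile normalization, where the median was −0.08 and the list did not pass (0.193). Without control replicates 1, 2 or 3 that count was 3, 1 or 2, and without MED1 siRNA replicate 3 it was 2. After median-ratio scaling it was 5, and after the GC and length correction 3, with a median of −0.07 (adjusted p 0.0337).

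Of 16 immediate early genes 9 were higher and 0 lower (limma, 0 lower also at an unadjusted p under 0.05), with a median of 0.47 (adjusted p 1.90e-07, and 0.0996 with an estimated correlation). The median was 0.31 with a minimum mean of 5 RPKM. CEBPB went from 14.9 ± 0.963 to 27.5 ± 0.133 RPKM and JUNB from 42.6 ± 2.54 to 78.2 ± 5.65 RPKM. Circadian clock genes were higher in 8 of 13 cases (median 0.34, adjusted p 7.15e-05, and 0.160 with an estimated correlation), among them PER1, from 6.37 ± 0.115 to 12.0 ± 1.13 RPKM, and the nuclear receptor NR1D1, from 3.72 ± 0.226 to 9.11 ± 2.02 RPKM. That count was 5 without control replicate 3 or MED1 siRNA replicate 3 and 3 with a minimum mean of 5 RPKM (median 0.13, adjusted p 0.0116), and the labels give no hour of harvest. Among 12 core subunits of RNA polymerase II, POLR2A, the catalytic subunit, rose from 20.1 ± 1.03 to 45.7 ± 7.35 RPKM (log2 fold change 1.14, adjusted p 0.000929). Only 1 other subunit passed, and it was lower. The lower count was 0 without any 1 of the 3 control replicates, without MED1 siRNA replicate 3, without a filter, with either smaller pseudocount and under both other scalings. It was 2 without MED1 siRNA replicate 2 and with a robust prior, and 2 were higher after quantile normalization. The polymerase list as a whole did not pass (median −0.03, adjusted p 0.865). Its median was 0.01 without control replicate 1, −0.05 without MED1 siRNA replicate 1, 0.02 after median-ratio scaling and 0.08 after quantile normalization or the GC and length correction. Targets of NRF2, to which HMOX1 belongs, gave 3 higher and 3 lower of 14 and did not pass (median 0.08, adjusted p 0.295). Their higher count was 5 without MED1 siRNA replicate 2, and their lower count was 1 without control replicate 2 or MED1 siRNA replicate 3. Under both other scalings 5 were higher, and after quantile normalization 1 was lower. Their median was 0.02 without control replicate 3, 0.03 without MED1 siRNA replicate 1 and 0.14 without MED1 siRNA replicate 3, and it was 0.12 and 0.15 after median-ratio scaling and quantile normalization and 0.12 with identical symbols collapsed.

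The fall of G2/M genes was weighed against 3 technical explanations, with bounds set before the results of these tests were seen. The fall itself was known when the bounds were set, and the GC and length correction was chosen after the data were seen. The list median was −1.33 after the GC and length correction and −1.38 after quantile normalization, and the highest median without any library was −1.30, all below the bound of −1. These values argue against GC or length bias, scaling or a single library as the whole cause. A lower share of dividing cells with MED1 siRNA is a candidate explanation that these bulk libraries do not test further, and a change in cell density between wells stays open.

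The fall of interferon-stimulated genes was largest in MED1 siRNA replicate 2, but the list median was still −0.51 without it. The medians of the other MED1 siRNA libraries, −0.613 and −0.430, lay below the lowest control median of −0.137 by more than the SD of the control medians (0.151), which argues against that library as the whole cause. After the GC and length correction the median was −0.80, which argues against that bias. Whether the siRNAs or the transfections themselves changed interferon activation was not tested, because each siRNA was given to a single group, and it stays open beside an effect of MED1 loss.

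For the fall of endothelial surface and junction genes, the list median was −0.50 after the GC and length correction, which argues against that bias. It was −0.41 after median-ratio scaling (camera, adjusted p 8.71e-06) and −0.29 after quantile normalization (adjusted p 2.06e-04). Under quantile normalization the highest MED1 siRNA library median, −0.191, lay below the lowest control median of −0.031 by more than the SD of the control medians (0.0439). Median-ratio scaling shifts all genes of a library nearly alike, so camera, which compares a list with the other genes, could hardly change under it. Both camera values also used the preset correlation, and with the estimated one the list did not pass on the deposited scale (camera, adjusted p 0.658). The list and library medians alone argue against scaling as the whole cause, although the size of the fall depends on it. Growth of other cells was weighed with every listed marker, of which those under a mean of 1 RPKM were not tested for change. Of 12 smooth muscle and pericyte markers 7 stayed under 10 RPKM with MED1 siRNA. Of the 6 tested 2 were higher and 2 lower, and only ACTA2 was both higher and above that level. Only 1 was higher without any library other than MED1 siRNA replicate 1, and 0 were lower without control replicate 2, control replicate 3, MED1 siRNA replicate 1 or MED1 siRNA replicate 3. MCAM, among the lower ones, is also a member of the endothelial list. Its fall is part of the pattern and does not count against such cells. MYH11 was at 0.139 ± 0.0325 and PDGFRB at 0.0304 ± 0.0129 RPKM with MED1 siRNA. Other markers were abundant in both groups. RGS5 went from 79.8 ± 1.63 to 92.9 ± 22.8 RPKM and SMTN from 21.8 ± 1.63 to 24.1 ± 1.46 RPKM, neither of them called. TAGLN was called lower, from 174 ± 24.1 to 96.7 ± 34.0 RPKM. Of 23 fibroblast, leukocyte and epithelial markers 20 stayed under 10 RPKM. Of the 5 tested 1 was higher and 3 lower, and 0 were both higher and above it (limma, 0 also at an unadjusted p under 0.05). The higher count was 0 without control replicate 2, control replicate 3 or MED1 siRNA replicate 3. POSTN, CD68 and KRT18 were above it in both groups and none of them rose. This argues against such cells as the whole cause, while a change of ACTA2 within the cells stays open.

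Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many called genes as the real grouping, which was the real split itself with 3664 genes, and the highest other split gave 2. With 10 splits the share cannot fall under 0.05. Each other split mixes libraries of both groups, so the group difference adds to the spread within its sides and few calls follow from the design. The contrast of 3664 with 2 is therefore no measure of chance. Groups did not overlap for 5675 of the tested genes, or 46.1%, where 10% is the share for a single gene whose libraries are exchangeable. Genes of a library move together, so these shares do not test whether the difference arose by chance.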
